A study of Mus musculus with 96 samples.

How the data were processed

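Bulk mRNA was sequenced from the cerebellum, cortex and hippocampus of mice, as 96 libraries from 38 animals. Per the labels' protocols, RNA was purified on RNeasy columns, amplified by Smart-Seq2 and made into libraries with Nextera XT, which does not mark strand. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.3.7 and aligned with STAR 2.5.3a to GRCm38, and DESeq2 was used with no version or role stated. The deposited table holds a raw count per gene symbol and library, with no normalization, and neither the counting tool nor its annotation is given in the sources used here. It lists 35486 gene symbols, of which 6251 have 0 counts in every library, and 35047 matched the reference gene names. All columns were matched to a sample by the labels.

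Groups were taken from the labels, by region, treatment, age and experiment. Labels with the same animal number in the cerebellum, cortex and hippocampus belong to the same mouse. A second number in the titles differs between naive and PBS mice, between ages and between the groups with 24 injections, and cannot be separated from those comparisons. Plasma and PBS mice share a number in part at 18 months (plasma replicates 10 and 13 with PBS replicate 11) and at 22 months (the 3 plasma mice with PBS replicate 21), and all 9 mice of the second experiment share 1 number. Comparisons, tests, gene lists, the rule for the named genes and the first set of alternatives were fixed before the data were examined. Leaving out libraries under 2500000 counts, leaving out libraries whose own-region neuron marker score lay more than 3 median absolute deviations below the median of the region, adding choroid plexus and marker scores as covariates, and other size factors for the gene lists were alternatives chosen after seeing the data.

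Counts were analysed in R 4.3.3. Each region was fitted with all its libraries of the first experiment, 29, in edgeR 4.0.16 with TMM factors, filterByExpr (minimum count of 10, minimum total of 15) and the quasi-likelihood test, 1 coefficient per group. The second experiment, with 9 libraries, was fitted alone, and the 18 hippocampus libraries at 18 months of both experiments were fitted together with the experiment as a covariate. Differences between regions were interaction contrasts over 87 libraries. P values were adjusted by the Benjamini-Hochberg method over all genes of a fit, with a threshold of 0.05, and the change of a gene is given as log2 fold change with its standard error. With no change in any gene, a share of about 0.05 of the genes is expected at an unadjusted p under 0.05. CPM are counts scaled to a total of 1000000 per library with no prior count, and log2 CPM used a prior count of 2. The tests tried as alternatives were DESeq2 1.42.0 and limma-voom with sample quality weights in limma 3.58.1. The other alternatives were relative log expression size factors, no filter on low counts, a fit of the compared groups alone, a fit with the mouse as a block and each library left out in turn. As a further alternative for plasma at 18 months in the first experiment, the 3 mice with the number shared by its PBS and plasma groups were left out.

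The named genes were, for the age comparison at 18 months and the plasma comparisons at 18 months, up to 8 genes per direction with the largest change among those past the threshold, with groups that do not overlap, a mean of at least 5 CPM and a symbol that is not a clone name, and up to 4 past the threshold from each list. Other comparisons took 4 per direction and 2 per list, and C4b, Gfap, Serpina3n, Fkbp5, Ttr and Fos were followed in every comparison. For differences between regions, which compare 4 groups, no criterion on overlap was applied. Some genes that met this rule are not reported here, and counts and gene lists include them. Tested gene lists had at least 3 expressed members, which left 30 of the 31 fixed lists, and 4 list members are absent from the table. Lists were tested with camera at a preset correlation of 0.01 and again with the correlation estimated from the residuals, and adjusted over the lists of a comparison. Plasma changes were set against age changes by the covariance over age genes, with every regrouping of the plasma and PBS libraries as an exact permutation.

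Whether animals deviate together across regions was checked on the deviations from group means. The median correlation was 0.039 between cerebellum and cortex, 0.0491 between cerebellum and hippocampus and 0.0917 between cortex and hippocampus. The pairing itself comes from the labels, which give the same animal. The regions were fitted without the block and with it as an alternative.

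The depth per library was 851288 to 23768385 counts. PCR duplicates cannot be told apart without molecular identifiers, so counts carry amplification noise beyond counting error. The scripts were tested on simulated counts with 200 changed genes drawn from the real means and depths. The changed genes had a mean count over 20, and counts were drawn gene by gene. In the age comparison of the cerebellum, 94% of genes changed 2-fold and 22% of genes at the smallest change simulated were recovered, and 4 of 154 calls fell on unchanged genes. In the age comparison of the hippocampus 76% and 8% were recovered, and 7 of 125 calls fell on unchanged genes.

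Positions are from the GRCm38 annotation. Without strand, counts of overlapping genes cannot be separated. Among the named genes, Irf7 overlaps Phrf1, Ctss overlaps Hmgb1-ps5, Gpr17 overlaps Lims2, B2m overlaps Patl2, Cd52 overlaps Crybg2, Cxcl10 overlaps Art3, Per3 overlaps Camta1, Rnf207 overlaps Icmt and Sfi1 overlaps Drg1. Pcdhb9 and Pcdhb14 belong to a cluster of similar genes, as do the class I genes H2-K1, H2-Q6 and H2-Q7, and their counts may mix copies. Alignment was not repeated, and reads were not used here.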

Results

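The series measured gene expression by mRNA sequencing in 96 brain libraries from 38 male C57BL/6J mice. In a first experiment, the cerebellum, cortex and hippocampus of 29 mice were each sequenced. In a second experiment, the hippocampus of 9 further mice was sequenced. The first experiment held untreated (naive) mice of 2 months (4 mice) and 18 months (3 mice). It also held 18-month mice given 7 daily injections of PBS, the saline vehicle (4 mice), or of plasma from young mice (5 mice), and 22-month mice given the same injections of PBS (3 mice) or plasma (3 mice). Mice of 19 months had 24 daily injections of PBS (4 mice) or plasma (3 mice), called long PBS and long plasma here. The second experiment held 18-month mice with 7 injections of PBS (4 mice) or plasma (5 mice). The young mice are labelled 2 months, while the description of the series gives 3 months.

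The total count per library ran from 851288 to 23768385, with a median of 8889509. The median was 6434791 in the cerebellum, 12287626 in the cortex and 9093296 in the hippocampus. Gabra6, a GABA receptor subunit of cerebellar granule cells, had a median of 405 CPM (counts scaled to a total of 1000000 per library) in the cerebellum and 0 CPM in the cortex and hippocampus. Prox1, a transcription factor of dentate granule cells, had a median of 83.5 CPM in the hippocampus and 16.4 CPM in the cortex. In 7 libraries the markers of the own region lay far below the others, among them the hippocampus library of naive 2-month replicate 14, with 17.2 CPM of Prox1. Another 7 libraries, 1 of them also in that set, had fewer than 2500000 counts. Among these were the cerebellum library of PBS 18-month replicate 2, with 1029695 counts, and the cortex library of naive 18-month replicate 3, with 1815609.

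**Figure D1:**
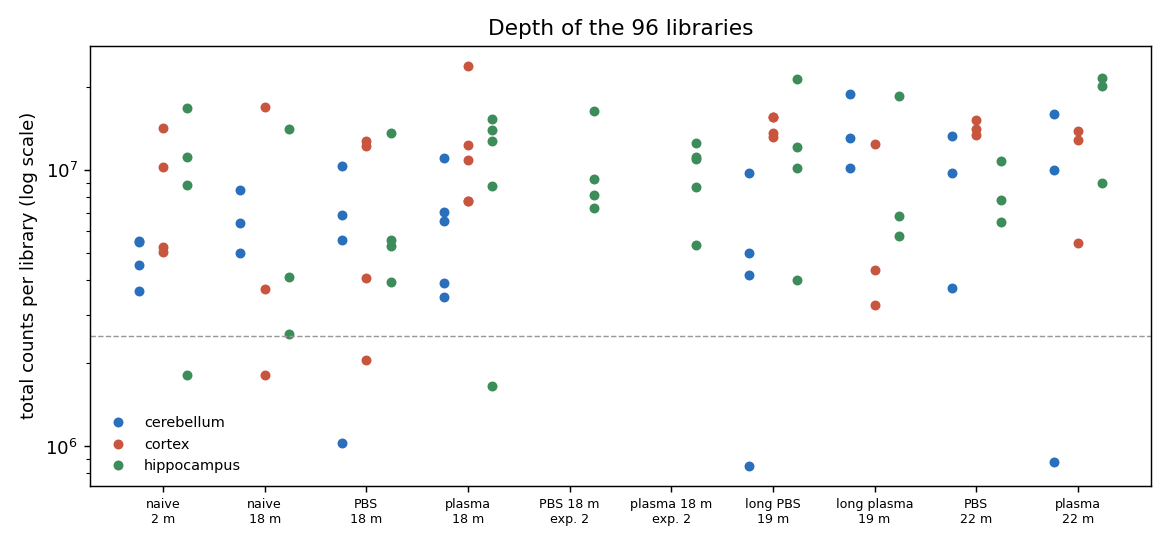
Total counts per library (vertical axis, logarithmic), by region and group, with 1 point per library. Libraries span 851288 to 23768385 counts, and 7 of the 96 fall under the dashed line at 2500000.

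The comparison of naive mice at 18 and 2 months addressed how each region changes with age before any injection. In the cerebellum, genes of complement, antigen presentation, interferon response and microglia were higher in the older mice. C4b, which encodes a complement component and lies on chromosome 17 from 34728380 to 34743882 in GRCm38, rose 4.38-fold, from 9.16 ± 2.22 CPM (SD, n = 4) to 40.8 ± 2.89 CPM (SD, n = 3). Irf7, a regulator of interferon genes, rose by 2.16 ± 0.40 on the log2 scale (SE), and the interferon-induced Ifit1 and Oasl2 rose by 1.97 ± 0.37 and 1.78 ± 0.36. Bst2, an antiviral membrane protein, and Gbp6, an interferon-induced GTPase, rose by 1.63 ± 0.39 and 1.62 ± 0.30. Lyz2, the lysozyme of myeloid cells, rose by 1.81 ± 0.32, and the kinase gene Ptk2b by 1.72 ± 0.28. The adjusted p values of these 8 genes in edgeR's quasi-likelihood test ran from 1.26e-10 for C4b to 0.0147 for Bst2.

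Several immune and glial gene lists fixed in advance were higher in the cerebellum at 18 months. Of the 24 tested interferon response genes, 24 were higher at 18 months, 13 passed over all genes and 19 passed adjusted over the list alone, with a median log2 change of 1.20. Antigen presentation genes had a median of 1.14, and 10 of 15 passed (13 adjusted over the list alone), among them H2-K1 (1.02 ± 0.10), B2m (0.92 ± 0.11) and the transporter gene Tap2 (0.84 ± 0.13). H2-Q7 rose from 0.489 ± 0.335 CPM (SD, n = 4) to 5.08 ± 0.81 CPM (SD, n = 3). All 8 complement genes tested were higher, and 6 passed (6 adjusted over the list alone), including the 3 chains of C1q, C1qa (1.29 ± 0.17), C1qb (1.02 ± 0.12) and C1qc (1.24 ± 0.17). Activated microglia genes had a median of 1.30, and 9 of 17 passed (13 adjusted over the list alone), among them the lysosomal proteases Ctss (1.43 ± 0.15) and Ctsd (0.43 ± 0.07). Cd52, a small surface protein of leukocytes, rose from 0.201 ± 0.181 CPM (SD, n = 4) to 1.85 ± 0.765 CPM (SD, n = 3). Of the 12 homeostatic microglia genes, 3 passed (8 adjusted over the list alone), among them Cx3cr1 (0.70 ± 0.12) and Tmem119 (0.85 ± 0.21). Ifi27 (1.47 ± 0.22) and Lgals3bp (1.56 ± 0.27) were further interferon-induced genes that rose. In the inflammatory cytokine list 2 of 7 genes passed (4 adjusted over the list alone). Ccl12, a chemokine, was listed at 0 in all 4 young libraries and at 1.30 ± 0.628 CPM (SD, n = 3) at 18 months, and Cxcl10 went from 0.0911 ± 0.182 CPM (SD, n = 4) to 1.62 ± 1.34 CPM (SD, n = 3). Gfap, an intermediate filament of astrocytes, rose by 0.47 ± 0.10, the 1 reactive astrocyte gene of 13 that passed (4 adjusted over the list alone). Each of these 7 lists also held in camera, a test of a list against all other genes, when the correlation among members was estimated. The camera adjusted p values with an estimated correlation were 0.00989 for interferon response, 0.00164 for antigen presentation, complement and activated microglia, 0.00737 for homeostatic microglia, 0.0338 for cytokines and 0.0411 for reactive astrocytes.

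Single genes of oligodendrocytes and of the matrix were lower in the cerebellum at 18 months, while the lists of myelin, oligodendrocyte precursor and matrix genes gave no call that held with an estimated correlation. Gpr17, a receptor of oligodendrocyte precursors committed to differentiate, fell by 1.30 ± 0.21, from 20.5 ± 4.32 CPM (SD, n = 4) to 8.54 ± 0.57 CPM (SD, n = 3). Of the 12 myelin genes, 6 fell (7 adjusted over the list alone), among them Ugt8a (-0.67 ± 0.13), Cldn11 (-0.56 ± 0.10) and Mog (-0.53 ± 0.11). The myelin list had a median of -0.30, with a camera adjusted p = 1.02e-08 at the preset correlation and an adjusted p = 0.0888 with an estimated correlation. Mkrn3, an imprinted gene, fell by 2.02 ± 0.30, and Zfp57, which protects imprints, fell from 7.09 ± 1.1 CPM (SD, n = 4) to 2.98 ± 0.736 CPM (SD, n = 3). Ntf3, a neurotrophin, fell by 1.64 ± 0.26, and Tnc, a matrix glycoprotein, by 1.33 ± 0.25. Car9, a carbonic anhydrase, fell by 1.27 ± 0.27, the glycosyltransferase gene Gcnt1 by 1.11 ± 0.22 and Necab3 by 1.01 ± 0.14. Smaller falls passed for the collagen gene Col1a1 (-0.87 ± 0.23), the endothelial lipid transporter gene Mfsd2a (-0.96 ± 0.25), the basement membrane gene Nid1 (-0.77 ± 0.17), Cdkn1a (-0.65 ± 0.16), Calb2 (-0.39 ± 0.09), Hmgcs1 (-0.33 ± 0.09), Gabra6 (-0.31 ± 0.06) and Slc1a3 (-0.23 ± 0.06). The clock genes Per2 (0.64 ± 0.16), Per3 (0.48 ± 0.09), Bhlhe41 (0.36 ± 0.06) and Hlf (0.34 ± 0.07), and the transcription factor gene Zbtb20 (0.33 ± 0.07), rose. Errors in this paragraph on the log2 scale are SE, with 3 older and 4 young mice, and each gene passed edgeR's test.

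The other lists gave no call in the cerebellum that held with an estimated correlation. Choroid plexus and ependyma genes had a median of 1.01 with 12 of 12 higher and 0 passing, camera adjusted p = 1.2e-05 and adjusted p = 0.17 with an estimated correlation. Their level varied between dissections, since Ttr, the main choroid plexus transcript, was at 328 ± 459 CPM (SD, n = 4) in the young and 1140 ± 223 CPM (SD, n = 3) in the older cerebella. Ribosomal protein genes had a median of 0.13 (camera adjusted p = 2.03e-06, adjusted p = 0.365 with an estimated correlation). Clock genes had a median of 0.14 (camera adjusted p = 0.00355, adjusted p = 0.0645 with an estimated correlation) and hippocampal neuron genes 0.16 (camera adjusted p = 0.0283, adjusted p = 0.0995 with an estimated correlation). Lower medians were found for oligodendrocyte precursors (-0.24; camera adjusted p = 0.000383, adjusted p = 0.0888 with an estimated correlation) and cholesterol synthesis (-0.14; camera adjusted p = 0.000909, adjusted p = 0.109 with an estimated correlation). The glucocorticoid response list had -0.17 (camera adjusted p = 0.0207, adjusted p = 0.325 with an estimated correlation) and immature neurons -0.18 (camera adjusted p = 0.0415, adjusted p = 0.17 with an estimated correlation). Synaptic genes had -0.11 (camera adjusted p = 0.00627, adjusted p = 0.159 with an estimated correlation), astrocyte markers -0.09 (camera adjusted p = 0.0499, adjusted p = 0.271 with an estimated correlation), oxidative phosphorylation -0.08 (camera adjusted p = 0.000909, adjusted p = 0.353 with an estimated correlation) and cerebellar neurons -0.07 (camera adjusted p = 0.0048, adjusted p = 0.325 with an estimated correlation). No call was made by camera for immediate early genes (adjusted p = 0.64), interneurons (0.307), endothelium (0.7), mural cells and fibroblasts (0.7), erythroid cells (0.267), mitochondrially encoded genes (0.872), heat shock and chaperones (0.0698), collagens and extracellular matrix (0.404), cortical neurons (0.7), or striatal and thalamic neurons (0.343). For endothelium the test pointed down and the median was 0.07, and for cortical neurons the test pointed up and the median was -0.05. A list of lymphocytes and plasma cells had too few expressed members to be tested.

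Across the 17185 genes tested in the cerebellum, 411 passed an adjusted p of 0.05 in edgeR, 228 higher and 183 lower. DESeq2 called 347 and limma-voom 678. Leaving out naive 18-month replicate 6 gave 194 genes, naive 18-month replicate 9 gave 247 and naive 2-month replicate 12 gave 243. C4b has a near-identical neighbour in C4a and H2-Q7 in H2-Q6, so the split of counts between such copies is uncertain.

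In the cortex the same age comparison gave fewer genes. Spag6, a gene of motile cilia, rose 2.97-fold, from 3.17 ± 0.789 CPM (SD, n = 4) to 9.73 ± 1.90 CPM (SD, n = 3), and Neat1, a nuclear long noncoding RNA, rose 2.23-fold, from 48 ± 9.5 to 109 ± 11.6 CPM (SD). The protocadherin genes Pcdhb14 and Pcdhb9 rose by 0.94 ± 0.15 and 0.94 ± 0.16 on the log2 scale (SE), Rnf207 by 0.73 ± 0.14, Ass1, an enzyme of arginine synthesis, by 0.66 ± 0.13, and Sfi1, a centrin-binding protein gene, by 0.65 ± 0.09. The class I antigen presentation genes H2-K1 and H2-Q7 rose by 0.73 ± 0.15 and 2.68 ± 0.55. Gpr17 fell by 1.27 ± 0.21, Zfp57 by 1.03 ± 0.21, Mfsd2a by 0.84 ± 0.15 and Ncan, a proteoglycan of the brain matrix, by 0.39 ± 0.08. C4b was at 26.8 ± 8.07 CPM (SD, n = 3) against 9.62 ± 3.41 CPM (SD, n = 4), and did not pass (edgeR adjusted p = 0.351). Of the 15 antigen presentation genes all were higher, 2 passed (9 adjusted over the list alone) and the median was 0.76 (camera adjusted p = 3.72e-13, adjusted p = 0.00543 with an estimated correlation). The cytokine list had a median of 0.37 with 7 of 7 higher (camera adjusted p = 0.00233, adjusted p = 0.0424 with an estimated correlation). Another 10 lists passed camera at the preset correlation alone. Among them were the interferon response (median 0.45, adjusted p = 0.113 with an estimated correlation), complement (median 0.22, adjusted p = 0.0935 with an estimated correlation) and activated microglia (median 0.21, adjusted p = 0.228 with an estimated correlation).

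Of 18769 genes tested in the cortex, 21 passed in edgeR, 16 higher and 5 lower, with 1160 at an unadjusted p under 0.05. DESeq2 called 32 genes, limma-voom 13 and a fit of these groups alone 5. Leaving out 1 library gave 3 genes (naive 18-month replicate 6), 5 (replicate 9), 8 (naive 2-month replicate 12) and 10 (replicate 14), and leaving out libraries under 2500000 counts gave 13. Of the 13 genes named here as passing, Spag6 passed under every alternative.

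In the hippocampus, complement and microglial genes rose with age. C4b rose 4.92-fold, from 25.1 ± 9.00 CPM (SD, n = 4) to 129 ± 38.8 CPM (SD, n = 3), and the further complement gene C1qa rose by 0.54 ± 0.11 on the log2 scale (SE). Ctss rose by 0.77 ± 0.13 and Il33, an alarmin cytokine made by glia, by 1.05 ± 0.17. Neat1 rose by 1.39 ± 0.22, the transporter gene Abca8a by 1.14 ± 0.22, Prrg1 by 1.06 ± 0.21 and Gatm, an enzyme of creatine synthesis, by 0.83 ± 0.16. H2-Q6 went from 0.273 ± 0.245 CPM (SD, n = 4) to 3.42 ± 1.02 CPM (SD, n = 3). Gpr17 fell by 0.85 ± 0.12, so that it was lower at 18 months in all 3 regions. Gfap was at 600 ± 102 CPM (SD, n = 3) against 385 ± 117 CPM (SD, n = 4), and did not pass (edgeR adjusted p = 0.581). Complement genes had a median of 0.31, and 2 of 10 passed (4 adjusted over the list alone; camera adjusted p = 1.97e-07, adjusted p = 0.0104 with an estimated correlation). Activated microglia genes had a median of 0.35 (camera adjusted p = 1.13e-07, adjusted p = 0.0404 with an estimated correlation) and cytokines 0.36 (camera adjusted p = 0.0103, adjusted p = 0.0479 with an estimated correlation). Genes of immature neurons and neurogenesis were lower, 9 of 9, with a median of -0.37 and 1 passing adjusted over the list alone (camera adjusted p = 8.96e-05, adjusted p = 0.0227 with an estimated correlation). Another 5 lists passed camera at the preset correlation alone, among them antigen presentation (median 0.64, adjusted p = 0.114 with an estimated correlation) and myelin (median 0.36, adjusted p = 0.42 with an estimated correlation).

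Of 18070 genes tested in the hippocampus, 13 passed in edgeR, 12 higher and 1 lower, with 1155 at an unadjusted p under 0.05. DESeq2 called 24 genes, limma-voom 10 and a fit of these groups alone 0. Leaving out 1 library gave 2 genes (naive 18-month replicate 6), 3 (replicate 3), 6 (replicate 9), 6 (naive 2-month replicate 12), 5 (replicate 14) and 8 (replicate 20). Naive 2-month replicates 14 and 20 are 2 of the libraries whose hippocampal markers lay far below the others. Without the libraries of that kind Abca8a, Prrg1, Gatm and H2-Q6 did not pass (edgeR adjusted p = 0.189, 0.0939, 0.155 and 0.094). The list medians were then 0.37 for complement (camera adjusted p = 1.88e-07), 0.55 for activated microglia (camera adjusted p = 4.21e-06), 0.59 for cytokines (camera adjusted p = 0.00155) and -0.36 for immature neurons (camera adjusted p = 0.000683), and that of cortical neurons went from -0.42 to 0.45.

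**Figure D2:**
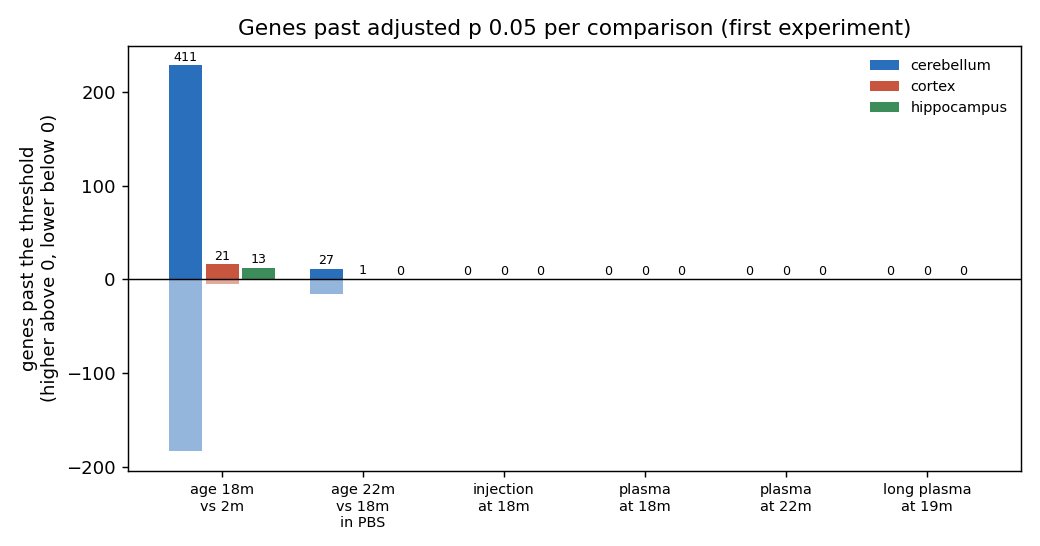
Number of genes past an adjusted p of 0.05 in edgeR for each comparison and region of the first experiment, with higher genes above 0 and lower genes below 0. The cerebellum has 411 genes in the age comparison at 18 against 2 months, and the plasma comparisons have 0.

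The age changes of the regions were compared directly, because a gene that passes in 1 region and not in another is not thereby shown to differ. Microglial and complement genes changed less in the cortex than in the cerebellum. The difference in log2 age change, cortex minus cerebellum, was -1.20 ± 0.21 (SE) for Ctss, -1.07 ± 0.22 for C1qc, -0.99 ± 0.20 for C1qa, -0.82 ± 0.16 for C1qb, -1.02 ± 0.22 for Tmem119, -1.49 ± 0.28 for the leukocyte gene Cyth4 and -1.68 ± 0.36 for Fam163b. With the mouse as a block Tmem119 and Fam163b did not pass here (adjusted p = 0.0818 and 0.0515). All 12 homeostatic microglia genes had a negative difference, with a median of -0.63 (camera adjusted p = 1.21e-11, adjusted p = 0.012 with an estimated correlation). Activated microglia genes had a median of -0.72 (camera adjusted p = 1.67e-08, adjusted p = 0.0139 with an estimated correlation) and complement genes -0.46 (camera adjusted p = 8.31e-06, adjusted p = 0.0139 with an estimated correlation). For hippocampus minus cerebellum the difference was -1.34 ± 0.26 for Fcer1g, an Fc receptor chain of myeloid cells, -1.10 ± 0.22 for C1qc, -1.13 ± 0.19 for Trank1, -1.70 ± 0.36 for Fam163b and 0.48 ± 0.11 for Uqcc1, which did not pass with the mouse as a block (adjusted p = 0.074). Without the libraries whose own-region markers lay far below the others, C1qc and Uqcc1 did not pass for hippocampus minus cerebellum (adjusted p = 0.11 and 0.0877). Myelin genes had a median difference of 0.73 there, with 12 of 12 positive (camera adjusted p = 9.98e-12, adjusted p = 0.297 with an estimated correlation). C4b did not differ past the threshold, at -0.66 ± 0.50 for cortex minus cerebellum and 0.17 ± 0.46 for hippocampus minus cerebellum (edgeR adjusted p = 1 and 0.999).

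Of 19490 genes, 8 passed in edgeR for cortex minus cerebellum, all lower, and 10 for hippocampus minus cerebellum, 1 higher and 9 lower. With the mouse as a block these counts were 8 and 9, and DESeq2 called 12 and 12. For hippocampus minus cortex 0 genes passed in edgeR, with 889 at an unadjusted p under 0.05 and 0 in DESeq2, and 1 passed without naive 2-month replicate 17. Leaving out a mouse gave 1 to 6 genes for cortex minus cerebellum, with 1 without naive 18-month replicate 9, 2 without replicate 6, 4 without replicate 3, and 2, 4 and 5 without naive 2-month replicates 12, 14 and 17. For hippocampus minus cerebellum it gave 5, 4 and 1 without naive 18-month replicates 3, 6 and 9, and 0 without naive 2-month replicate 14.

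The comparison of PBS-injected mice at 22 and 18 months addressed changes late in life. In the cerebellum C4b rose by 0.80 ± 0.12 on the log2 scale (SE), from 39.1 ± 1.4 CPM (SD, n = 4) to 69.3 ± 0.723 CPM (SD, n = 3), and Gfap, on chromosome 11 from 102887336 to 102900912 in GRCm38, rose by 0.54 ± 0.10, from 262 ± 16.3 CPM to 382 ± 20.4 CPM (SD). The microglial genes Cx3cr1 and Ctsd rose by 0.51 ± 0.11 and 0.35 ± 0.07, Cd83 by 0.57 ± 0.12 and Wdr35, a gene of ciliary transport, by 0.62 ± 0.13. Banp fell by 0.63 ± 0.12, the neuronal splicing factor gene Srrm4 by 0.58 ± 0.11, the immediate early gene Ier2 by 0.55 ± 0.12, Neb by 0.51 ± 0.11 and Prox1 by 0.41 ± 0.09. Activated microglia genes had a median of 0.40, with 17 of 17 higher, 1 passing over all genes and 9 adjusted over the list alone (camera adjusted p = 3.34e-07, adjusted p = 0.152 with an estimated correlation). Interferon response genes had a median of 0.48 (camera adjusted p = 1.81e-06, adjusted p = 0.239 with an estimated correlation). Immediate early genes had a median of -0.73 with 13 of 15 lower (camera adjusted p = 0.000174, adjusted p = 0.269 with an estimated correlation).

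In the cortex Etv1, a transcription factor of layer 5 neurons on chromosome 12 from 38779380 to 38870484 in GRCm38, rose by 0.65 ± 0.10, from 59.5 ± 2.5 CPM (SD, n = 4) to 95.6 ± 14.4 CPM (SD, n = 3). C4b was at 62.5 ± 15.4 CPM (SD) at 22 months and 23.5 ± 7.68 CPM at 18 months (edgeR adjusted p = 0.17), and Gfap at 250 ± 55.3 CPM and 116 ± 28.8 CPM (edgeR adjusted p = 0.0759). In the hippocampus C4b was at 138 ± 9.65 CPM (SD, n = 3) and 89.7 ± 3.76 CPM (SD, n = 4), and did not pass (edgeR adjusted p = 0.516). Myelin genes in the hippocampus had a median of 0.60, with 12 of 12 passing adjusted over the list alone and 0 over all genes (camera adjusted p = 4.05e-10, adjusted p = 0.707 with an estimated correlation). Of the 4 hippocampus libraries of PBS at 18 months, replicates 5 and 11 had hippocampal markers far below the others, with Prox1 at 44.4 and 44.5 CPM, and none of the 3 at 22 months did. Without libraries of that kind the myelin median was 0.52 (camera adjusted p = 3.14e-08). In the cortex, mitochondrially encoded genes had a median of -0.20 with 13 of 13 lower (camera adjusted p = 0.00041, adjusted p = 0.504 with an estimated correlation). Synaptic genes had -0.12 (camera adjusted p = 0.000635, adjusted p = 0.267 with an estimated correlation).

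In edgeR 27 genes passed in the cerebellum, 11 higher and 16 lower, 1 in the cortex and 0 in the hippocampus, with 2605, 2048 and 1419 at an unadjusted p under 0.05. DESeq2 called 120, 49 and 1, and limma-voom 292, 6 and 24. In the cerebellum the count was 1 without PBS 18-month replicate 2, 5 or 8, 247 without replicate 11, the 1 mouse of that group with another second number in its title, and 2, 54 and 1 without PBS 22-month replicates 21, 15 and 18. C4b passed under every alternative there and Gfap under 8 of 15. In the cortex the count was 0 without PBS 18-month replicate 2, 8 or 11, 2 without replicate 5, and 2, 5 and 2 without PBS 22-month replicates 21, 15 and 18.

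**Figure D3:**
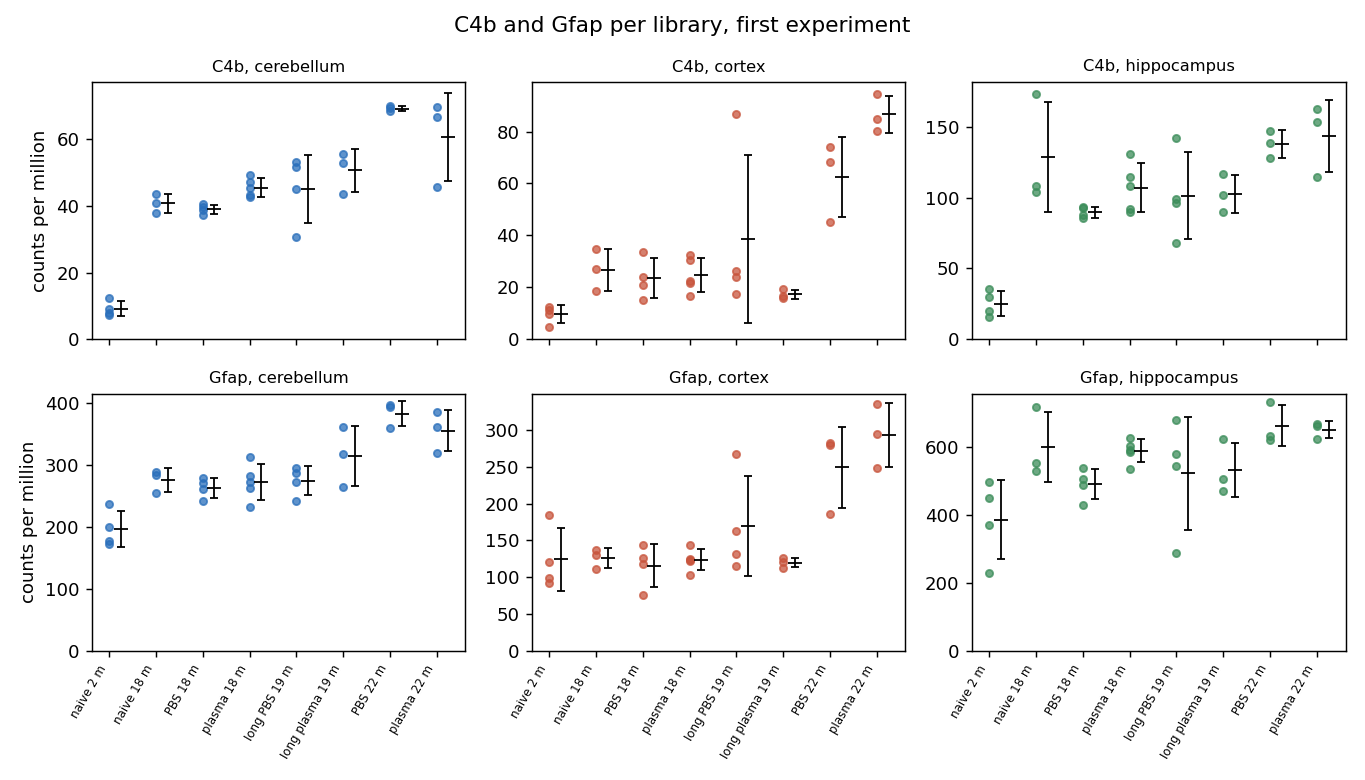
C4b and Gfap in CPM (vertical axes) by region and group of the first experiment, with 1 point per library, the group mean and its SD. C4b is at 9.16 CPM in the cerebellum of young mice and 40.8 CPM at 18 months.

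The comparison of 18-month mice given PBS with naive mice of the same age addressed the injections themselves. C4b in the cerebellum was at 39.1 ± 1.4 CPM (SD, n = 4) after PBS and 40.8 ± 2.89 CPM (SD, n = 3) in naive mice. In the hippocampus it ran from 85.45 to 93.1 CPM after PBS and from 104.3 to 173.5 CPM in naive mice, and did not pass. Fos, an immediate early gene, was at 18.1 ± 3.72 CPM (SD, n = 4) and 35.5 ± 5.81 CPM (SD, n = 3) in the hippocampus, and Fkbp5, a target of glucocorticoids, at 60.7 ± 4.31 and 57.3 ± 6.88 CPM (SD), and neither passed. Myelin genes in the hippocampus had a median of -0.57 after PBS, with 12 of 12 lower, 0 passing over all genes and 10 adjusted over the list alone (camera adjusted p = 3.53e-11, adjusted p = 0.33 with an estimated correlation). Activated microglia genes had medians of -0.26 in the cerebellum (camera adjusted p = 6.02e-05, adjusted p = 0.269 with an estimated correlation) and -0.38 in the hippocampus (camera adjusted p = 1.41e-05, adjusted p = 0.33 with an estimated correlation). PBS replicates 5 and 11 had low hippocampal markers (Prox1 at 44.4 and 44.5 CPM) and none of the 3 naive 18-month libraries did. Without libraries of that kind the hippocampal medians were -0.49 for myelin (camera adjusted p = 3.92e-08) and -0.39 for activated microglia (camera adjusted p = 8.9e-06). Immediate early genes in the cortex were lower in 17 of 17, with a median of -0.33 (camera adjusted p = 0.00206, adjusted p = 0.599 with an estimated correlation). No single gene passed in edgeR in the cerebellum, cortex or hippocampus (0, 0 and 0), with 571, 681 and 639 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. A fit of these groups alone called 15 genes in the hippocampus, and 1 gene passed in the cortex without naive 18-month replicate 3.

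The comparison of 18-month mice after 7 days of young plasma with those after PBS addressed whether plasma alters aged brain tissue. In the cerebellum C4b was at 45.5 ± 2.75 CPM (SD, n = 5) after plasma and 39.1 ± 1.4 CPM (SD, n = 4) after PBS, a log2 difference of 0.22 ± 0.11 (SE, edgeR adjusted p = 1). In the cortex it was at 24.6 ± 6.58 and 23.5 ± 7.68 CPM (SD), and in the hippocampus at 107 ± 17.1 and 89.7 ± 3.76 CPM (SD). Gfap in the hippocampus was at 588 ± 34.1 CPM after plasma and 491 ± 45.5 CPM after PBS (SD), a difference of 0.27 ± 0.18 (SE, edgeR adjusted p = 1). Serpina3n, an acute-phase gene of reactive astrocytes, was at 35.1 ± 5.88 and 33 ± 8.33 CPM (SD) in the hippocampus, and Fkbp5 at 73.5 ± 6.85 and 60.7 ± 4.31 CPM (SD). Ttr in the hippocampus was at 512 ± 1080 CPM (SD, n = 5) after plasma and 44.3 ± 45.7 CPM (SD, n = 4) after PBS, with 2440 CPM in plasma replicate 7. Antigen presentation genes had a positive difference in 15 of 15 in the hippocampus, with a median of 0.49, 0 passing over all genes and 1 adjusted over the list alone (camera adjusted p = 0.000108, adjusted p = 0.597 with an estimated correlation). Interferon response genes had a median of 0.38 in the hippocampus (camera adjusted p = 0.00318, adjusted p = 0.666 with an estimated correlation). Erythroid genes, markers of blood, had a median of 1.68 in the hippocampus (camera adjusted p = 0.00492, adjusted p = 0.597 with an estimated correlation). The low hippocampal markers of PBS replicates 5 and 11 (Prox1 at 44.4 and 44.5 CPM) were found in none of the 5 plasma libraries. Without libraries of that kind the medians were 0.49 for antigen presentation (camera adjusted p = 0.00729), 3.06 for erythroid genes (camera adjusted p = 0.0065) and 0.29 for the interferon response, which no longer passed (camera adjusted p = 0.183). Activated microglia genes had a median of 0.25 in the cerebellum (camera adjusted p = 0.00056, adjusted p = 0.369 with an estimated correlation). In the cortex 0 of 30 lists passed.

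No gene passed in edgeR in the cerebellum, cortex or hippocampus (0, 0 and 0), with 696, 762 and 440 at an unadjusted p under 0.05. These were 4.05%, 4.06% and 2.43% of the genes tested, less than the share of 0.05 expected with no change. DESeq2 and limma-voom also called 0 in each. In data simulated for these comparisons, 98% of genes changed 2-fold were recovered in the cerebellum, 82% in the cortex and 84% in the hippocampus. These shares were 84%, 64% and 56% of genes changed 1.5-fold, and 26%, 22% and 14% of genes at the smallest change simulated. The changed genes had a mean count over 20, and the simulated libraries held no structure apart from the groups. The shares may therefore overstate recovery in the real libraries. The plasma changes were also compared between regions, and 0 genes passed in edgeR for each of the 3 differences, with 844 for hippocampus minus cerebellum, 949 for hippocampus minus cortex and 615 for cortex minus cerebellum at an unadjusted p under 0.05 and 0 in DESeq2.

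The second experiment repeated the plasma treatment in the hippocampus at 18 months. C4b was at 124 ± 56 CPM (SD, n = 5) after plasma and 81.9 ± 20.1 CPM (SD, n = 4) after PBS, a log2 difference of 0.63 ± 0.26 (SE, edgeR adjusted p = 0.604). Serpina3n was at 37.2 ± 5.19 and 29.3 ± 6.35 CPM (SD), a difference of 0.38 ± 0.13 (SE, edgeR adjusted p = 0.602). Ribosomal protein genes had a positive difference in 48 of 49, with a median of 0.21 and 0 passing (camera adjusted p = 2.32e-16, adjusted p = 0.742 with an estimated correlation). Lars2, a gene singled out after its values were seen, also differed there in its share of counts, for a cause that was not tested. It took 6.64 ± 0.633% of the counts after plasma (SD, n = 5) and 4.67 ± 0.779% after PBS (SD, n = 4, exact permutation p = 0.0238), against 3.96 ± 0.7% and 3.66 ± 0.501% (SD) in the first experiment (exact permutation p = 0.5). Heat shock and chaperone genes had a positive difference in 16 of 16, with a median of 0.21, 0 passing over all genes and 4 adjusted over the list alone (camera adjusted p = 9.86e-07, adjusted p = 0.357 with an estimated correlation). Choroid plexus genes had a median of 0.62 (camera adjusted p = 0.00322, adjusted p = 0.803 with an estimated correlation), with Ttr at 1250 ± 805 CPM (SD, n = 5) after plasma and 764 ± 1460 CPM (SD, n = 4) after PBS. Cortical neuron genes had a median of -0.31 (camera adjusted p = 0.00975, adjusted p = 0.742 with an estimated correlation). With both experiments together and the experiment as a covariate, C4b was 0.46 ± 0.16 (SE) higher after plasma (115 ± 40 CPM, SD, n = 10, against 85.8 ± 14 CPM, SD, n = 8, edgeR adjusted p = 0.357) and Gfap 0.24 ± 0.08 higher (edgeR adjusted p = 0.326), neither of which passed. Complement genes had a positive difference in 10 of 10, with a median of 0.19 and 4 passing adjusted over the list alone (camera adjusted p = 0.00118, adjusted p = 0.373 with an estimated correlation). Ribosomal protein genes had a median of 0.13 in the joint fit (camera adjusted p = 9.18e-18, adjusted p = 0.373 with an estimated correlation).

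In the second experiment 0 genes passed in edgeR (1363, or 7.96%, at an unadjusted p under 0.05), while DESeq2 called 21 and limma-voom 0, and edgeR called 1 without PBS replicate 70. In the joint fit 0 genes passed in edgeR (1679, or 9.56%, at an unadjusted p under 0.05), while DESeq2 called 55, 19 higher and 36 lower, and limma-voom 1. Without PBS replicate 70 of the second experiment edgeR called 14 genes in the joint fit, without PBS replicate 2 of the first 6, and without PBS replicate 8 or plasma replicate 7 of the first or plasma replicate 76 of the second 1 each. The plasma changes of the experiments differed for 0 genes in edgeR, with 545 at an unadjusted p under 0.05 and 0 in DESeq2. Between the experiments, antigen presentation genes differed by a median of -0.60, second minus first, with 15 of 15 negative (camera adjusted p = 0.00331, adjusted p = 0.855 with an estimated correlation).

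At 22 months, 7 days of plasma were compared with PBS in 3 mice each. In the cortex C4b was at 86.6 ± 7.18 CPM (SD) after plasma and 62.5 ± 15.4 CPM after PBS, a log2 difference of 0.47 ± 0.36 (SE, edgeR adjusted p = 0.936), and of 0.29 ± 0.39 (SE) without PBS replicate 18. In the cerebellum it was at 60.7 ± 13.1 and 69.3 ± 0.723 CPM (SD), and in the hippocampus at 143 ± 25.4 and 138 ± 9.65 CPM (SD). Interferon response genes in the cortex had a median of 0.32 (camera adjusted p = 0.000391, adjusted p = 0.302 with an estimated correlation) and antigen presentation genes 0.28 (camera adjusted p = 0.00235, adjusted p = 0.302 with an estimated correlation). Genes of striatal and thalamic neurons, which mark tissue from outside the cortex, had a median of -1.24 there (camera adjusted p = 4.85e-05, adjusted p = 0.302 with an estimated correlation). Myelin genes had a median of 0.28 in the cortex (camera adjusted p = 0.00235, adjusted p = 0.6 with an estimated correlation) and -0.26 in the hippocampus (camera adjusted p = 0.000186, adjusted p = 0.995 with an estimated correlation). In edgeR 0 genes passed in the cerebellum, cortex and hippocampus, with 392, 1059 and 304 at an unadjusted p under 0.05. DESeq2 called 0, 0 and 1, limma-voom 0 in each, and a fit of these groups alone called 3 in the cerebellum. The plasma change at 22 months differed from that at 18 months for 0 genes in each region in edgeR, with 625, 1391 and 505 at an unadjusted p under 0.05 and 0, 0 and 1 in DESeq2. Without plasma 22-month replicate 22, 1 gene passed for that difference in the cerebellum.

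After 24 days of injections at 19 months, C4b in the cortex was at 17.3 ± 1.84 CPM (SD, n = 3) with plasma and 38.5 ± 32.3 CPM (SD, n = 4) with PBS, a log2 difference of -1.15 ± 0.40 (SE, edgeR adjusted p = 1), with long PBS replicate 24 at 86.6 CPM. Without that library the difference was -0.38 ± 0.28 (SE). In the cerebellum C4b was at 50.7 ± 6.39 and 45.1 ± 10.3 CPM (SD), and in the hippocampus at 103 ± 13.4 and 101 ± 30.6 CPM (SD). Homeostatic microglia genes had a negative difference in 12 of 12 in the cortex, with a median of -0.24 and 1 passing adjusted over the list alone (camera adjusted p = 4.02e-05, adjusted p = 0.49 with an estimated correlation), and in 12 of 12 in the hippocampus, with a median of -0.15 (camera adjusted p = 1.18e-05, adjusted p = 0.336 with an estimated correlation). Cholesterol synthesis genes in the hippocampus had a negative difference in 16 of 16, with a median of -0.13 (camera adjusted p = 3.55e-06, adjusted p = 0.336 with an estimated correlation). Choroid plexus genes had medians of 1.51 in the cerebellum (camera adjusted p = 0.000203, adjusted p = 0.792 with an estimated correlation) and 1.45 in the hippocampus (camera adjusted p = 1.95e-05, adjusted p = 0.726 with an estimated correlation). In the hippocampus, long plasma replicate 23 and long PBS replicate 24 had Prox1 at 25 and 22.2 CPM, far below the median of 83.5 CPM. No gene passed in edgeR in the cerebellum, cortex or hippocampus (0, 0 and 0), with 1147, 660 and 706 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. Without long PBS replicate 28, 1 gene passed in the cerebellum.

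**Figure D4:**
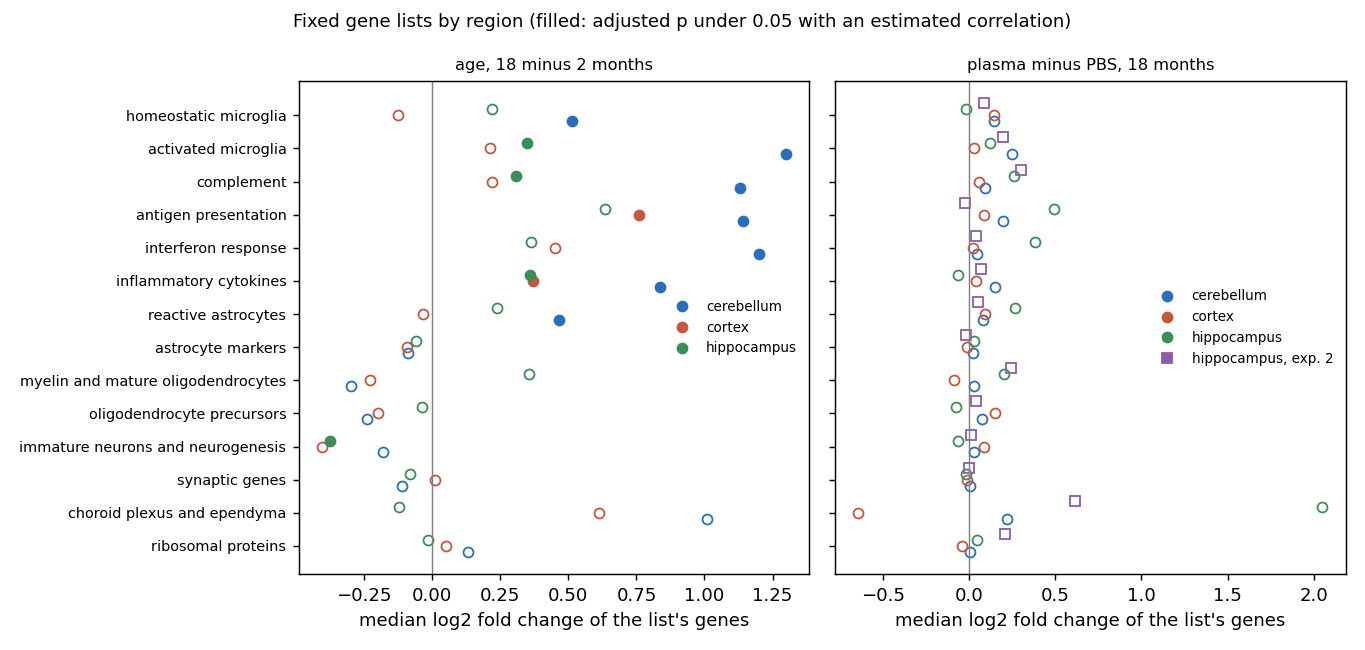
Median log2 fold change (horizontal axis) of 14 fixed gene lists for the age comparison (left) and the plasma comparison at 18 months (right) in the 3 regions, with squares for the second experiment and filled symbols for camera adjusted p under 0.05 with an estimated correlation. In the cerebellum the interferon response list has a median of 1.20 with age.

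The title of the series speaks of rejuvenation, so the plasma changes were set against the age changes, gene by gene. Of the 411 age genes of the cerebellum, 40.4% had a plasma change at 18 months opposite to their age change, 45.7% at 22 months and 51.3% after long plasma. Genes that rose with age in the cerebellum had a median plasma log2 change of 0.04 at 18 months, 0.02 at 22 months and -0.02 after long plasma. Of the 21 age genes of the cortex, 47.6%, 23.8% and 42.9% were opposite in these comparisons, and of the 13 age genes of the hippocampus, 23.1%, 69.2% and 46.2%. In the second experiment 23.1% of the 13 were opposite, and in both experiments together 30.8%. The covariance of age and plasma changes over the age genes was tested by an exact two-sided permutation of the plasma and PBS libraries, in each of these comparisons. The smallest p was 0.119, for the hippocampus at 18 months, where the covariance was positive, and the Benjamini-Hochberg adjusted values were 0.88 or more. With 3 mice in each group the smallest p such a permutation test can give is 0.1. The genes that rose with age in the hippocampus were also higher after plasma at 18 months, by a median of 0.11 (camera p = 0.0224 across genes, p = 0.226 with an estimated correlation), and in both experiments together by 0.08 (camera p = 0.0126, p = 0.184 with an estimated correlation). In the second experiment alone the median was 0.09 (camera p = 0.123, p = 0.459 with an estimated correlation), and the covariance was negative (-0.0741, exact permutation p = 0.706). These camera p values were not adjusted over the comparisons. Chance cannot be excluded for the count of 13 age genes itself, since 3 of 35 groupings, the real one included, gave as many. Naive mice gave the age changes and injected mice the plasma changes, so the comparisons share no library.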

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

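The tests chosen only after the results were seen were the ratio of depths, the spread between cortex libraries and the removal of shallow libraries for the microglial genes, the removal of libraries with low own-region markers and the other groupings of the cerebellum libraries, while the thinned counts and the groupings elsewhere were set beforehand. The age change differed between regions by a test of the difference itself. It differed for 8 genes for cortex minus cerebellum, with log2 differences of -1.68 for Fam163b, -1.49 for Cyth4, -1.20 for Ctss, -1.07 for C1qc, -1.02 for Tmem119, -0.99 for C1qa and -0.82 for C1qb, of which Fam163b and Tmem119 did not pass with the mouse as a block. The lists that differed had medians of -0.63 for homeostatic microglia, -0.72 for activated microglia and -0.46 for complement. Of the 35 groupings of the 7 mice, 1 gave as many as 8 genes, the real one, and the highest of the others gave 2. That is the smallest share 35 groupings can give, and it argues against chance for this count. For hippocampus minus cerebellum it differed for 10 genes, among them with -1.70 for Fam163b, -1.34 for Fcer1g, -1.13 for Trank1, -1.10 for C1qc and 0.48 for Uqcc1. Of these Uqcc1 did not pass with the mouse as a block, and C1qc and Uqcc1 did not pass without the libraries whose own-region markers lay far below the others. There 6 of 35 groupings gave as many genes and the highest other gave 215, so chance cannot be excluded. The 215 genes came with naive 18-month replicate 6 and naive 2-month replicates 14 and 20 set apart, and these last 2 are hippocampus libraries with low hippocampal markers, which points to a structure of the samples, whose cause was not tested.

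The smaller age change of microglial and complement genes in the cortex, a median difference of -0.66 ± 0.17 (SE) over 39 members, was weighed against depth and spread. The naive cortex libraries had a median depth 0.959 times that of the cerebellum, so lower depth stays possible by that value alone. With the 14 naive libraries thinned to 1815609 counts each, the median difference was -0.59 ± 0.13 (SE), against -0.66 unthinned. Without the shallow libraries it was -0.63 ± 0.23. That the median hardly moved argues against unequal depth and against a shallow library as the cause. The errors in this paragraph are taken over genes and hold no spread between mice. A larger spread between the cortex libraries stays open, because the median log2 ratio of the SD within groups, cortex over cerebellum, was -0.046 ± 0.194 (SE) over 36 members and leaves either sign possible. A difference between the tissues in how microglia age also stays open and was not tested here.

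Single libraries stood apart from the rest of their group in 15 of 180 cases tested by the gap to the nearest library relative to the range, and chance alone gives about 1 in 20. Groups of 3 libraries were not tested in this way. Ttr, the choroid plexus transcript, accounted for several of the 15 cases in the hippocampus. It was at 2440 CPM in plasma 18-month replicate 7 (others 9.57 to 44), 2440 CPM in long PBS replicate 29 (others 6.51 to 149), 2960 CPM in PBS replicate 70 of the second experiment (others 21 to 50.9) and 217 CPM in naive 2-month replicate 17 (others 4.52 to 28.9). The hippocampus of long plasma mice, a group of 3 that was not tested, had Ttr at 4609 CPM in replicate 23, 2549 CPM in replicate 27 and 29.3 CPM in replicate 25. In the cortex Ttr was at 110 CPM in PBS 18-month replicate 2 (others 13 to 23). Long PBS replicate 29 also had Fos at 36.1 CPM in the hippocampus (others 23.2 to 23.8) and Fkbp5 at 15.3 CPM in the cerebellum (others 8.61 to 9.1). In the cortex, C4b was at 86.6 CPM in long PBS replicate 24 (others 17.6 to 26.1), and plasma 18-month replicate 1 had 23768385 counts (others 7719401 to 12287626). In the cortex of naive 2-month mice, replicate 20 had Ass1 at 20.2 CPM (others 24.5 to 24.9) and H2-Q7 at 1.52 CPM (others 0.198 to 0.294), and replicate 12 had Sfi1 at 27.9 CPM (others 31.2 to 31.8). In the cerebellum, naive 2-month replicate 14 had Necab3 at 55.2 CPM (others 42.3 to 44.4) and Cxcl10 at 0.365 CPM (others 0), and PBS 18-month replicate 8 had Wdr35 at 18 CPM (others 23.3 to 24.4).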

How the results depend on the processing

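The tests chosen only after the results were seen were the fits without libraries under 2500000 counts, the fits without libraries whose own-region markers lay far below the others, the fits with choroid plexus and marker scores as covariates, and other size factors for the gene lists. Of the 51 genes that met the naming rule for age in the cerebellum at 18 months, 31 passed under every alternative run there. The count of 411 stayed within 1.5 times under DESeq2 and the other model settings and rose to 678 in limma-voom. Of the genes that met the rule and passed elsewhere, 1 of 13 in the cortex, 0 of 11 in the hippocampus, and 1 of 12 in the cerebellum and 0 of 1 in the cortex at 22 against 18 months passed under every alternative. For the age differences between regions 0 of 7 for cortex minus cerebellum and 0 of 6 for hippocampus minus cerebellum did, and none of these genes changed direction. The plasma comparisons at 18 months in the first experiment had 0 genes under every alternative run in the cerebellum, cortex and hippocampus. In limma-voom with sample quality weights the count at 22 against 18 months was 292 in the cerebellum, 6 in the cortex and 24 in the hippocampus, with 13 for age at 18 months in the cortex and 1 for plasma in both experiments. In DESeq2 the count at 22 against 18 months was 120 in the cerebellum, 49 in the cortex and 1 in the hippocampus. The age comparison at 18 months gave 32 genes in the cortex and 24 in the hippocampus in DESeq2, and plasma in the hippocampus gave 21 in the second experiment, 55 in both, 1 at 22 months and 1 for 22 minus 18 months. With relative log expression factors the cerebellum at 22 against 18 months had 15 genes. With no filter on low counts it had 312, the cortex had 10, and plasma at 22 minus 18 months in the cerebellum had 2. Without libraries under 2500000 counts the counts at 22 against 18 months were 1 in the cerebellum and 0 in the cortex, and those for age at 18 months were 13 in the cortex and 8 in the hippocampus. Without libraries whose own-region markers lay far below the others, 5 genes passed at 22 against 18 months in the cortex, 1 for the age difference of hippocampus minus cortex and 17 for cortex minus cerebellum. With the marker and choroid plexus scores as covariates, 8 genes passed in the cerebellum and 54 in the cortex at 22 against 18 months, and 34 in the cortex and 8 in the hippocampus for age at 18 months. With only the groups compared in the fit, 483 genes passed in the cerebellum, 0 in the cortex and 15 in the hippocampus at 22 against 18 months. That fit also gave 5 genes in the cortex and 0 in the hippocampus for age at 18 months, 15 for the injections in the hippocampus and 3 for plasma at 22 months in the cerebellum. For these moves the cause was not tested.

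With 1 library left out in turn, the count for age at 18 months ran from 194 (naive 18-month replicate 6) to 350 (naive 2-month replicate 17) in the cerebellum, from 3 (naive 18-month replicate 6) to 19 (naive 18-month replicate 3) in the cortex and from 2 (naive 18-month replicate 6) to 9 (naive 2-month replicate 17) in the hippocampus. At 22 against 18 months it ran from 1 (PBS 18-month replicate 2, among others) to 247 (PBS 18-month replicate 11) in the cerebellum and from 0 (PBS 18-month replicate 2, among others) to 5 (PBS 22-month replicate 15) in the cortex. The range was 0 to 1 for long plasma (long PBS replicate 28) and for plasma at 22 minus 18 months (plasma 22-month replicate 22) in the cerebellum, for the injections in the cortex (naive 18-month replicate 3), for plasma in the second experiment (PBS replicate 70) and for the age difference of hippocampus minus cortex (naive 2-month replicate 17). It was 0 to 14 for plasma in both experiments (PBS replicate 70 of the second), 0 (naive 2-month replicate 14) to 9 (naive 2-month replicate 17) for the age difference of hippocampus minus cerebellum, and 1 (naive 18-month replicate 9) to 6 (naive 2-month replicate 20) for cortex minus cerebellum. In the other comparisons it was 0 throughout, and leaving out the 3 mice with the shared title number, run for plasma at 18 months in the 3 regions of the first experiment alone, left those counts at 0.

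With the mouse as a block, which pairs the regions of an animal, the age difference gave 9 genes for hippocampus minus cerebellum, 0 for hippocampus minus cortex and 8 for cortex minus cerebellum, and the plasma difference gave 0, 0 and 0. The lists past the threshold numbered 9, 5 and 10 for age and 2, 2 and 2 for plasma. The block ended the calls of Uqcc1 for hippocampus minus cerebellum and of Fam163b and Tmem119 for cortex minus cerebellum, and changed no other call among the named genes. The block applies to differences between regions alone.

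For the gene lists, an estimated correlation left 7 lists for age in the cerebellum, 2 in the cortex, 4 in the hippocampus and 3 for cortex minus cerebellum, and 0 in every other comparison that had calls at the preset correlation. Without libraries under 2500000 counts the number of lists was 4 for plasma at 22 months in the cerebellum, 10 at 22 against 18 months in the cortex, and 5, 4 and 0 for the plasma differences of hippocampus minus cerebellum, hippocampus minus cortex and cortex minus cerebellum. Without libraries whose own-region markers lay far below the others it was 9 at 22 against 18 months in the cortex, 2 for plasma at 18 months in the cortex, and in the hippocampus 14 for age, 2 at 22 against 18 months, 12 for the injections and 5 for long plasma, with 0 for the plasma difference of hippocampus minus cerebellum. With the scores as covariates it was 0 for long plasma in the cerebellum, 3 for the injections in the cortex, and in the hippocampus 4 for plasma at 18 months, 7 at 22 months and 7 in both experiments. The choroid plexus list in the cerebellum went from a median of 1.01 to 0.03 with those scores, which by construction take out its own level.

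In the comparison of plasma with age, a threshold of 0.01 for the age genes reversed the direction in several cases. At 22 months in the cerebellum the exact permutation p was 0.6, and camera across genes gave 0.296 for genes higher and 0.915 for genes lower with age, all 3 reversed. After long plasma in the cerebellum the exact permutation p was 0.886, reversed, and camera across genes gave 0.0149 for genes lower with age. At 18 months in the cortex the exact permutation p kept its direction, and camera across genes gave 0.707 for genes lower with age, reversed. After long plasma in the cortex the exact permutation p was 0.0286 (Benjamini-Hochberg adjusted 0.157), with the plasma changes in the direction of age, and camera across genes gave 0.0312 for genes higher with age. In the second experiment the exact permutation p was 0.19, reversed, and camera across genes gave 0.011 for genes higher with age. In both experiments the permutation p was 0.0205 (Benjamini-Hochberg adjusted 0.157), again in the direction of age. Over all expressed genes the direction reversed at 18 months in the cortex (exact p = 0.111) and in the second experiment (exact p = 0.421). With an estimated correlation the camera value across genes higher with age was 0.226 in the hippocampus at 18 months and 0.184 in both experiments. For these changes the cause was not tested.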

Other observations

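The tests chosen only after the results were seen were those of cortex dissection, transcript length, choroid plexus tissue, the depth difference and Lars2, and the groupings of the cerebellum libraries, while the correlations with depth and the other groupings were set beforehand. Of 8 relations of C4b and Gfap tested across the 29 cortex libraries within groups with 20000 permutations, 3 passed an adjusted p of 0.05, those of C4b with myelin genes and of C4b and Gfap with synaptic genes. The Pearson r was 0.649 for C4b and myelin (permutation p = 0.0172, Benjamini-Hochberg adjusted 0.0459, Spearman rho 0.476 with permutation p = 0.045, r without the 2 most extreme libraries 0.433), -0.587 for C4b and synaptic genes (permutation p = 0.00135, adjusted 0.0054, rho -0.581 with permutation p = 0.00345, r without 2 libraries -0.587) and -0.695 for Gfap and synaptic genes (permutation p = 8e-04, adjusted 0.0054, rho -0.662 with permutation p = 0.00125, r without 2 libraries -0.622). White matter in the dissections may contribute to C4b, and hippocampal tissue stays open, since C4b with hippocampal markers (Pearson r = 0.414, permutation p = 0.0425, adjusted 0.068, rho 0.496 with permutation p = 0.0194, r without 2 libraries 0.425), Gfap with these (r = 0.366, permutation p = 0.137, adjusted 0.183, rho 0.42 with permutation p = 0.0797, r without 2 libraries 0.326) and Gfap with myelin (r = 0.575, permutation p = 0.0339, adjusted 0.0678, rho 0.399 with permutation p = 0.105, r without 2 libraries 0.316) did not pass. With myelin and hippocampal scores as covariates the C4b change from 18 to 22 months went from 1.36 ± 0.36 to 0.71 ± 0.24 (SE), and neither value passed (edgeR adjusted p = 0.577 with the scores). The remaining change lay more than 2 standard errors above 0. Because the scores may not take up all of the dissection, it cannot decide whether dissection is the whole cause. A rise of C4b with age stays open, and so does depth (C4b with log2 depth, Pearson r = 0.246, permutation p = 0.162, adjusted 0.185, rho 0.309 with permutation p = 0.123, r without 2 libraries 0.199), where the bound set beforehand, that a p of 0.05 or more excludes depth, was wrong, because a p that misses a threshold excludes nothing.

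Ribosomal protein genes had a median log2 difference of 0.21 after plasma in the hippocampus of the second experiment, and by mouse their score differed by 0.18 (exact permutation p = 0.0635). Changes there followed transcript length across genes (Spearman rho -0.235, against -0.00415 in the first experiment). Random lists matched on length and expression had a median of 0.13, with the list at their 99.99th percentile. Length may account for part of the difference. The random lists were drawn gene by gene and take no account of correlation among the members. That percentile therefore cannot decide whether length accounts for all of the difference. With the choroid plexus score as a covariate the median was 0.25 ± 0.02 (SE over genes, with no spread between mice). That it did not fall argues against choroid plexus tissue. A depth difference is argued against too, since mean log2 depth in units of 1000000 counts was 3.22 after plasma and 3.28 after PBS and carried 0.00282 ± 0.00563 (SE) of the 0.18, while the correlation of the score with log2 depth (Pearson r = -0.2, exact permutation p = 0.621) has a spread of 0.373 and decides nothing alone. The share of counts taken by Lars2, 6.64 ± 0.633% after plasma and 4.67 ± 0.779% after PBS (SD, exact permutation p = 0.0238), cannot be told apart from plasma, because the part of the difference that it carried was 0.0697 ± 0.137 (SE), too wide to decide, and the shares of plasma and PBS libraries hardly overlap.

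Other groupings of the same libraries were fitted for each remaining count of genes. For age at 18 months the counts argue against chance in the cerebellum (1 of 35 groupings gave as many as the real 411, highest other 123) and in the cortex (1 of 35, real 21, highest other 4). A share of 1 of 35 is the smallest these groupings can give. In the hippocampus chance cannot be excluded, since 3 of 35 gave as many as the real 13 and the highest other gave 270. That grouping set naive 18-month replicate 6 and naive 2-month replicates 14 and 20 apart. It points to a structure of the samples whose cause was not tested, since Prox1 in the hippocampus was at 17.2 and 29.2 CPM in replicates 14 and 20 and at 73.7 CPM in replicate 6. At 22 against 18 months chance cannot be excluded in the cerebellum (2 of 35, real 27). There the highest other gave 267 genes with PBS 18-month replicates 2, 5 and 8 set apart from replicate 11 and the 22-month mice. That grouping follows the second number in the titles, which replicates 2, 5 and 8 share and replicate 11 does not. It differs from the real grouping by replicate 11 alone. That number cannot be told apart from that mouse, and the cause was not tested. No such number occurs in both ages, so no value within a number can be had, and age and that number cannot be separated here. In the cortex 1 of 35 gave as many as the real 1 (highest other 0), the smallest share that 35 groupings can give. That count rests on Etv1, a gene that did not pass under 6 of 15 alternatives, so it does not exclude chance. In the hippocampus, with a real count of 0, 35 of 35 gave as many by construction (highest other 0), which decides nothing about chance.

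With a real count of 0 every grouping gives as many genes, so the counts below decide nothing about chance. For the injections 35 of 35 groupings gave as many as the real 0, with a highest other of 2 in the cerebellum, 1 in the cortex and 0 in the hippocampus. For plasma at 18 months 100 of 100 groupings drawn from 126 gave as many as the real 0, with a highest other of 44 in the cerebellum, 19 in the cortex, 1 in the hippocampus and 257 in the second experiment. In both experiments together and for their difference 100 of 100 drawn from 15876 did, with a highest other of 5 and 17. At 22 months the 10 groupings are too few, with 10 of 10 at the real 0 and a highest other of 0 in each region. After long plasma 35 of 35 gave as many as the real 0, with a highest other of 42 in the cerebellum, 1 in the cortex and 214 in the hippocampus. For plasma at 22 minus 18 months 100 of 100 drawn from 2520 did, with 6, 46 and 118 in the cerebellum, cortex and hippocampus. For the plasma differences between regions 40 of 40 drawn from 126 did, with 2 for hippocampus minus cerebellum and 0 for the others, and for age in hippocampus minus cortex 35 of 35 did, with 464. Groupings with 42, 44, 46, 118, 214, 257 and 464 genes where the real one had 0 point to a structure of the samples apart from the groups compared. The 214 genes came with long plasma replicates 23 and 27 and long PBS replicate 29 set apart. Their hippocampus libraries had Ttr at 4609, 2549 and 2442 CPM, against 6.51 to 149 CPM in the others, so that grouping follows choroid plexus tissue. The 464 genes came with naive 18-month replicates 3 and 6 and naive 2-month replicate 14 set apart. The hippocampus library of replicate 14 had low hippocampal markers (Prox1 at 17.2 CPM).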
